A study of Drosophila melanogaster with 13 samples.

How the data were processed

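RNA of adult fly heads was measured on Affymetrix Drosophila expression arrays, on which a probe set is a group of short probes that together measure a transcript. Flies were reared at 25 °C and 70% humidity and RNA was extracted with Trizol, per the labels' protocols. The deposited values are log2 expression per probe set, and RMA and limma are named for them per the submitters' processing notes, with versions and settings not given in the sources used here. RMA corrects background, normalises between arrays and summarises probes on the log2 scale, so differences between the values are log2 fold changes, and a change in the total RNA per head would not show in them.

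The series has 13 arrays in 4 groups, with 3 biological replicates per group per the labels, and the control's replicate 1 was hybridised to a technical pair of arrays. Values of 12 arrays were used. The second array of the pair had an empty column, so that replicate rests on its first array, and the planned averaging of the pair and the planned use of the second array alone were not run. All 12 columns were matched to samples by name. Of 18952 probe sets, 183 Affymetrix controls were left out and 18769 were tested. The platform annotation gave 13646 of these 1 gene symbol, 402 several and 4721 none, and genes were named only from the first class. The identifiers of 103 of the first class were absent from the annotation of Release 6 used for chromosomes. Altogether 11981 genes had a probe set, 1094 of them several, and 11892 were placed on a chromosome arm. For each gene the probe set with the highest mean over all arrays stood for it in lists and on chromosomes. Among genes with several probe sets past the threshold, both signs occurred in 32 of 577 in the egg mutant, 37 of 643 in the Su(var)3-9 mutant and 40 of 627 in the double mutant against the control, in 9 of 72 for the double against the egg mutant and in 4 of 23 for the double against the Su(var)3-9 mutant. Expression arrays do not give a depth, and their number limits the precision.

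A linear model with 4 group means was fitted to each probe set with limma (lmFit and eBayes, limma 3.58.1 in R 4.3.3), with 8 residual and 4.162 prior degrees of freedom. The contrasts were each mutant against the control, the double mutant against each single mutant, the interaction and both main effects. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each contrast, and calls used an adjusted p under 0.05. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6. The groups, the contrasts, the gene lists, the rule for named genes and all alternatives not named here as added were chosen before the data were examined.

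Gene lists were tested with camera with a correlation of 0.01 between genes, and again with an estimated correlation and with fry. None of the list calls of any contrast held with an estimated correlation. Lists needed 4 measured genes. They covered H3K9 methylation and heterochromatin, chromosome 4 (a list named by hand and all measured genes), pericentric genes (likewise), photoreceptors, eye pigment, the circadian clock, sex-enriched genes of either sex, head fat body, antimicrobial and immune genes, Turandot and heat shock genes, detoxification, odorant binding, neurons, glia, ribosomal proteins, the respiratory chain, the proteasome, chromosome arms, and other tissues (testis, ovary, muscle, gut). Pericentric windows reached from 22 Mb of 2L, 23 Mb of 3L and 22 Mb of X to the centromere side and up to 5.4 Mb of 2R and 4.5 Mb of 3R. An accessory gland list was added after the data were seen. Of 64 transposable elements 2 were named on the array, so that list was not tested. Chromosome arms were compared with two-sided Fisher's exact tests, and so were genes within 2 Mb of either mutated gene. Such tests count genes as independent, although all genes were measured on the same arrays.

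Named genes, each by its brightest probe set, were the 10 largest rises and 10 largest falls against the control among probe sets past the threshold with 1 symbol and no overlap between replicates, the 5 largest in each direction for other contrasts, up to 4 genes per list and up to 10 chromosome 4 or pericentric genes. Genes named outside this rule are said to be so. The alternatives were a replicate block, a fit of only the groups compared, trend and robust eBayes, array weights, removal of probe sets below the 40th percentile of mean signal, each array centred on its median or on the median of its brighter probe sets, cyclic loess, a 1.5-fold minimum, adjusted p under 0.01 or 0.1 for chromosome tests, the mean of a gene's probe sets, and leaving out each array in turn. Added after the data were seen were the other-tissue score as a covariate and the omission of Su(var)3-9 replicate 3 and double mutant replicate 2 together.

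The fit was tested on simulated data for the egg comparison, with 200 of 18769 probe sets changed. It recovered 52% of those changed by 0.5 and 95% of those changed by 1 on the log2 scale, with 155 calls in all, of which 8 were of unchanged probe sets, and made 0 calls in a contrast without changes. In a simulation of 32 lists with a shift of 0.2 for chromosome 4, that list and its hand list were called, 2 in all, and 0 in the unchanged contrast. Probe sets were simulated as independent, while the estimated correlation between chromosome 4 genes in the data was 0.146. The simulation therefore did not test list calls under such correlation.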

Results

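Adult heads of Drosophila melanogaster were profiled on Affymetrix expression arrays in 4 genotypes, so that transcript levels could be compared between flies with and without mutations in a pair of histone methyltransferase genes. The gene egg encodes the fly SETDB1 homolog and Su(var)3-9 encodes the fly homolog of SUV39H enzymes, and both proteins methylate histone H3K9, a mark of heterochromatin. The control was yw with the balancer chromosome CyO over a wild-type chromosome. The egg mutant carried 1 egg mutant chromosome over CyO, the Su(var)3-9 mutant carried the Su(var)3-9 mutation beside the control's second chromosome, and the double mutant carried both mutations. Each genotype was measured on 3 arrays, which the labels call biological replicates, giving 12 arrays. A total of 18769 probe sets was compared, with median log2 signals of 5.71 to 6.14 per array, and the number of arrays limits the precision. Values after ± are standard errors of the log2 change with n = 3 arrays per group unless stated otherwise. Genes were ranked by the brightest probe set of each, so that a dimmer or unnamed probe set may have changed more than those named as largest. No probe set used here was named for egg or Su(var)3-9, so the mutated genes were not analysed here and the genotype labels were not checked by them.

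The control heads stood apart from those of all 3 mutants in transcripts of other body parts. The median log2 signal of 22 testis genes was 8.78 or higher on each of the 3 control arrays and 6.71 or lower on each of the 9 mutant arrays. For 22 gut enzyme genes these limits were 10.72 and 8.24, and for 15 genes of flight and body muscle 12.37 and 11.50. For 26 accessory gland genes, a list chosen after the data were seen, they were 9.11 and 7.69. Neuronal and photoreceptor genes lay the other way, while 9 glia genes overlapped, with control arrays up to 9.82 and mutant arrays down to 9.72. The median of 13 head fat body genes averaged 10.19 in the control, 9.89 in the egg mutant, 10.49 in the Su(var)3-9 mutant and 10.85 in the double mutant. The median of 19 neuronal genes was 9.84 or lower in the control and 10.23 or higher in the mutants, and that of 22 photoreceptor genes 10.39 or lower and 10.57 or higher. The mean of the testis, gut and muscle medians is used below as the other-tissue score. It was 10.62 to 10.93 in the control, 8.54 to 8.57 in the egg mutant, 6.87 to 7.66 in the Su(var)3-9 mutant and 7.03 to 7.56 in the double mutant. Arrays of 1 genotype correlated at r = 0.992 to 0.998 across probe sets, which are not independent observations. The mean r with the control was 0.898 for the Su(var)3-9 mutant and 0.911 for the double mutant, against 0.990 between those mutants.

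**Figure D1:**
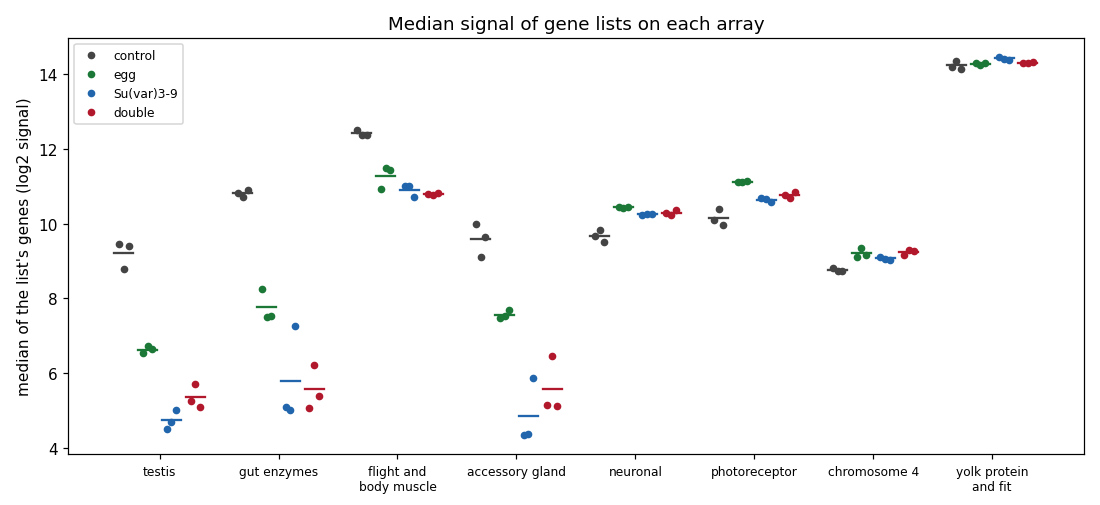
Median log2 signal of the measured genes of 8 lists on each of 12 arrays, with 1 point per array, colours for the 4 genotypes and a bar at the mean of the 3 arrays of a genotype. The testis list lies at 8.78 or above on the control arrays and at 6.71 or below on the mutant arrays, and the neuronal list lies at 9.84 or below and 10.23 or above.

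Heads of egg heterozygotes were compared with the control to ask what follows from losing 1 copy of egg. The control also had a higher other-tissue score, so a change cannot be credited to that loss alone. Genes of the small, largely heterochromatic chromosome 4 lay higher in the mutant. Of the 65 measured, 55 rose, 5 fell and 5 did not pass, with a median log2 change of 0.54, and under cyclic loess 36 rose and 8 fell. Among them CG31997 rose by 1.06 ± 0.06 (adjusted p = 1.38e-07) and CG32017 by 1.21 ± 0.10. The GABA transporter gene Gat rose by 1.04 ± 0.09 and the metabotropic glutamate receptor gene mGluR by 0.87 ± 0.09. The largest rises were those of the chorion gene Cp15 (3.93 ± 0.92, adjusted p = 0.00283) and of CG3397 (3.43 ± 0.12, adjusted p = 2.86e-09). The mean of Cp15 rests on uneven arrays, with a standard deviation of 2.74 in the egg mutant. The median of 23 ovary and germline genes was 5.79, 4.41 and 4.77 on egg replicates 1, 2 and 3. The largest fall was that of the mannosidase gene LManIII (-4.72 ± 0.60, adjusted p = 2.80e-05), followed by that of CG15617 (-4.60 ± 0.22).

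Other large rises were those of the amino acid transporter path (2.67 ± 0.13), the cell cycle gene Cks30A (2.65 ± 0.13), the midkine homolog miple1 (2.43 ± 0.08) and the cytochrome P450 gene Cyp6a17 (2.37 ± 0.09). A pair of scavenger receptor genes of blood cells also rose, Sr-CI by 2.65 ± 0.08 and Sr-CIII by 2.33 ± 0.10. The Jonah proteases Jon44E and Jon25Biii changed by -4.39 ± 0.44 and -4.30 ± 0.76, the maltases Mal-A4, Mal-A7 and Mal-A1 by -4.31, -3.63 and -3.62, and the mucin Muc68D by -4.07. The flight muscle genes TpnC4, a troponin C, and fln, flightin, changed by -4.36 ± 0.95 and -3.68 ± 0.90. In all, 9550 probe sets passed, 6000 of them higher and 3550 lower, and 472 and 1767 of these differed by at least 2-fold.

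The chromosome 4 list passed the camera test (adjusted p = 8.53e-07, adjusted p = 0.368 with an estimated correlation). Adjusted over the list alone, 55 genes were higher and 5 lower. Of 45 genes of this chromosome named in advance, 37 rose and 5 fell (adjusted p = 6.80e-05, adjusted p = 0.368 with an estimated correlation), or 22 and 7 under cyclic loess. Of 188 genes in pericentric windows, 93 rose and 37 fell, adjusted over the list alone 97 and 38. Their median of 0.22 turned to -0.01 under cyclic loess (adjusted p = 0.0485, adjusted p = 0.379 with an estimated correlation). That call was lost without control replicate 2 (adjusted p = 0.0879), egg replicate 2 (adjusted p = 0.0655), Su(var)3-9 replicates 1 (adjusted p = 0.0503) or 3, or double mutant replicate 2 (adjusted p = 0.0525 each). The mean of this list was 0.05, and COX4L fell by 2.81 ± 0.22 within it. With the other-tissue score as a covariate COX4L changed by -1.01 ± 0.58 and did not pass (limma adjusted p = 0.428). Of 21 pericentric genes named in advance, 15 rose and none fell (adjusted p = 0.0022, adjusted p = 0.368 with an estimated correlation), but under cyclic loess 7 rose and 1 fell. Examples were Haspin (1.13 ± 0.10), a histone H3 kinase, and Snap25 (0.84 ± 0.08), a synaptic fusion protein. In the list of 19 genes of H3K9 methylation and heterochromatin, 14 rose and 1 fell, adjusted over the list alone 16 and 1 (adjusted p = 0.00562, adjusted p = 0.368 with an estimated correlation), and under cyclic loess 6 and 1. The gene that fell was Pof (-2.21 ± 0.20), whose protein binds chromosome 4. Its change was -0.66 ± 0.55 with the other-tissue score as a covariate, and did not pass (limma adjusted p = 0.597). The SETDB1 cofactor wde (0.68 ± 0.09) and the kinase JIL-1 (0.99 ± 0.13) rose.

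Of the neuronal genes, 18 of 19 rose, with 0.99 ± 0.09 for the RNA-binding protein fne and 0.92 ± 0.09 for the vesicle protein Rab3 (adjusted p = 5.22e-06, adjusted p = 0.368 with an estimated correlation). Photoreceptor genes rose in 20 of 22 cases (adjusted p = 2.61e-05, adjusted p = 0.368 with an estimated correlation). Among them rdgC (1.28 ± 0.08), inaC (1.15 ± 0.09) and trp (0.94 ± 0.10) act in the light response. Genes of the clock rose in 10 of 11 cases, with Pdp1 at 1.46 ± 0.12 (adjusted p = 0.00163, adjusted p = 0.368 with an estimated correlation), and under cyclic loess 6 rose and 1 fell. Lists of other body parts fell in the same comparison. In the testis list 20 of 22 genes fell, with the protamine gene ProtA at -3.17 ± 0.22 (adjusted p = 1.92e-06, adjusted p = 0.368 with an estimated correlation). In the accessory gland list 22 of 26 fell (adjusted p = 1.03e-06, adjusted p = 0.368 with an estimated correlation). Muscle genes fell in 13 of 15 cases (adjusted p = 3.73e-05, adjusted p = 0.368 with an estimated correlation). Gut genes fell in 12 of 22 cases, adjusted over the list alone 15 (adjusted p = 0.000807, adjusted p = 0.425 with an estimated correlation). Adjusted over the list alone, 18 neuronal, 20 photoreceptor and 10 clock genes were higher, and 20 testis, 22 accessory gland and 13 muscle genes were lower, with 1 testis gene higher.

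Of 75 genes of the respiratory chain and ATP synthase, 68 fell and none rose in the egg mutant, with a median of -0.45 (adjusted p = 1.24e-16, adjusted p = 0.368 with an estimated correlation). With arrays centred on their medians 49 fell and 3 rose, with a median of -0.23. The list members ND-24L (-2.18 ± 0.11) and ATPsynCF6L (-2.76 ± 0.15) fell far more than the list median, in a comparison where testis genes fell too. Neither passed with the other-tissue score as a covariate, at -1.86 ± 0.39 and -2.20 ± 0.53 (limma adjusted p = 0.0685 and 0.101). Proteasome genes fell in 25 of 40 cases (adjusted p = 2.09e-06, adjusted p = 0.379 with an estimated correlation), among them Prosbeta5R1 (-2.38 ± 0.12) and Prosalpha6T (-2.32 ± 0.15), which are testis subunits. With arrays centred on their medians 14 proteasome genes fell and 1 rose, with a median of -0.06. Lower when adjusted over the list alone were 69 respiratory chain and 25 proteasome genes and 6 named chromosome 4 genes, while 37 of the latter and 16 named pericentric genes were higher. Higher calls made up 62.8%, against 80.4% with each array centred on its median, 51.0% with centring on brighter probe sets and 37.8% under cyclic loess. Centring on the median moved the median change of all probe sets from 0.09 to 0.32, and the chromosome 4 median was then 0.77, against 0.29 under cyclic loess. With the other-tissue score as a covariate, an alternative added after the data were seen, 113 probe sets passed and the median standard error rose from 0.103 to 0.367, and the chromosome 4 median over genes was then 0.547, while its list median per array changed by 0.478 ± 0.233, with a 95% interval that includes 0.

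**Figure D2:**
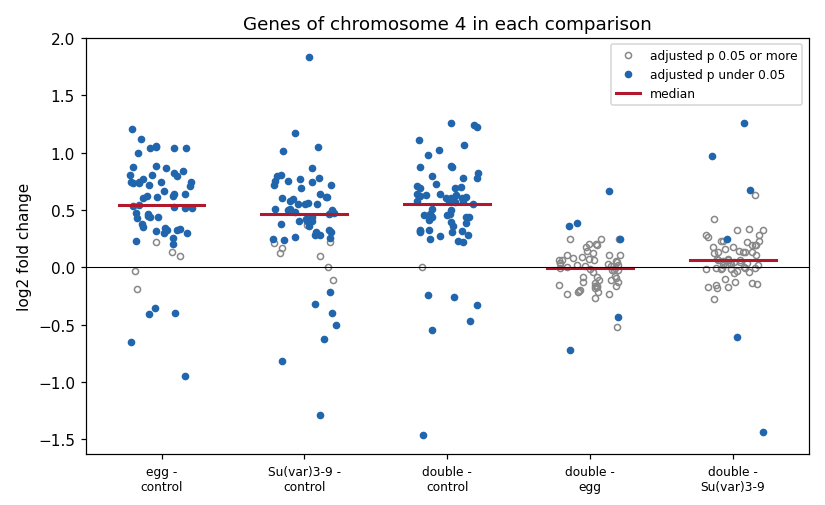
Log2 change of each of 65 chromosome 4 genes in 5 comparisons, with 1 point per gene, filled where the adjusted p of the limma test was under 0.05, and a line at the median. The medians are 0.54, 0.47 and 0.55 against the control, 0.06 for the double against the Su(var)3-9 mutant, and -0.01 for the double against the egg mutant, which was 0.12 with each array centred on its median.

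In heads of Su(var)3-9 mutants, a probe set without a gene name rose most against the control, by 6.74 ± 0.12. Of the genes, Fbp1 and Fbp2, which encode fat body proteins, rose most, by 3.90 ± 0.25 and 3.63 ± 0.29 (adjusted p = 5.67e-08 and 3.95e-07), and the stress gene TotC by 3.33 ± 0.21. The cuticle genes Cpr49Ac and Lcp65Ac rose by 3.27 ± 0.32 and 3.14 ± 0.12, the odorant binding protein gene Obp19a by 3.26 ± 0.16 and the antifungal peptide homolog Drsl5 by 3.12. The falls were largest for the ejaculatory bulb genes Ebp and EbpII, which fell by 7.64 ± 0.91 and 7.38 ± 0.74, the seminal protein genes Acp53C14b, Acp36DE, Acp53Ea and Dup99B by 7.09, 6.85, 6.79 and 6.74, and the testis gene ocn by 6.80 ± 0.51. Genes without a known role here included CG9616 (3.17 ± 0.08), CG3397 (2.98 ± 0.12) and l(3)mbn (2.97 ± 0.21) among the rises and lncRNA:CR9284 (-6.85), CG9920 (-6.83) and CG17376 (-6.80) among the falls.

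Chromosome 4 genes rose in 50 of 65 cases and fell in 7, adjusted over the list alone 53 and 7, with a median of 0.47 (adjusted p = 0.000477, adjusted p = 0.503 with an estimated correlation). Under cyclic loess 28 rose and 8 fell. The kinesin gene Kif3C rose by 1.84 ± 0.11, Rnf11 by 1.17 ± 0.08 and CG31997 by 1.01 ± 0.06. The glutamate receptor gene CG11155 fell by 0.82 ± 0.09. Of the 188 pericentric genes, 86 rose and 36 fell without a call for the list (adjusted p = 0.416), and their median of 0.18 became -0.07 under cyclic loess. CG14647 fell there by 2.37 ± 0.09, and the rRNA pseudogene 18SrRNA-Psi:CR41602 rose by 2.43 ± 0.12. The H3K9 list did not pass, with 11 genes higher and 1 lower (adjusted p = 0.239), or 4 and 5 under cyclic loess, and within it Pof fell by 3.38 ± 0.20. Pof changed by -0.86 ± 0.88 with the other-tissue score as a covariate (limma adjusted p = 0.874). Eye pigment genes rose in 13 of 18 cases (adjusted p = 0.0101, adjusted p = 0.377 with an estimated correlation). Among them se (1.36 ± 0.10) and pr (0.97 ± 0.09) act in pteridine synthesis. Neuronal genes rose in 18 of 19 cases, with ple, tyrosine hydroxylase, at 1.03 ± 0.11 (adjusted p = 0.000625, adjusted p = 0.515 with an estimated correlation). Photoreceptor genes rose in 15 of 22 cases without a call for the list (adjusted p = 0.0675), and the histamine receptor gene ort rose by 1.11 ± 0.08. Of these lists 13 eye pigment and 18 neuronal genes were higher adjusted over the list alone.

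Lists of other body parts fell again in this mutant. Testis genes fell in 20 of 22 cases with a median of -4.93 (adjusted p = 7.66e-11, adjusted p = 0.377 with an estimated correlation). Accessory gland genes fell in 25 of 26 cases with a median of -4.83 (adjusted p = 2.66e-13, adjusted p = 0.377 with an estimated correlation). Gut genes fell in 19 of 22 cases with a median of -4.70 (adjusted p = 5.46e-07, adjusted p = 0.503 with an estimated correlation), and muscle genes in 11 of 15 (adjusted p = 0.000437, adjusted p = 0.503 with an estimated correlation), or in 8 with 4 higher when arrays were centred on their medians. Respiratory chain genes fell in 69 of 75 cases, with a median of -0.42 and COX4L, a paralog of a cytochrome c oxidase subunit, at -4.79 ± 0.22 (adjusted p = 3.91e-18, adjusted p = 0.377 with an estimated correlation). With arrays centred on their medians only 26 fell and 7 rose, with a median of -0.045. COX4L fell far more than its list and changed by -1.86 ± 0.93 with the other-tissue score as a covariate (limma adjusted p = 0.707). Adjusted over the list alone, 20 testis, 25 accessory gland, 19 gut, 11 muscle and 71 respiratory chain genes were lower, and 1 gut and 2 respiratory chain genes higher. In all 11580 probe sets passed, 8325 higher and 3255 lower, of which 497 and 1847 changed at least 2-fold. Higher calls made up 71.9%, against 86.8% with each array centred on its median, 60.8% with centring on brighter probe sets and 38.7% under cyclic loess. Centring on the median moved the median change of all probe sets from 0.21 to 0.58, and the chromosome 4 median was then 0.84, against 0.20 under cyclic loess. With the other-tissue score as a covariate 10 probe sets passed, with a median standard error of 0.583. Among them CG8997 and Sgp, named outside the rule, turned from -5.62 to 8.82 and from -5.90 to 6.59. The chromosome 4 list median per array then changed by 0.353 ± 0.370, with a 95% interval that includes 0.

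The double mutant, with both mutations, was compared with the control. The other-tissue score also differed, at 7.03 to 7.56 against 10.62 to 10.93, so the changes cannot be credited to the mutations alone. Of 65 chromosome 4 genes 58 rose and 6 fell, with a median of 0.55, and under cyclic loess 31 rose and 6 fell. The gene with the largest rise was CG3397 (4.75 ± 0.12, adjusted p = 4.53e-10), which had also risen in both single mutants, followed by TotC (3.58 ± 0.21), Fbp2 (3.40 ± 0.29), the amino acid transporter path (3.29 ± 0.13) and Fbp1 (2.98 ± 0.25). CG11357 rose by 2.57 ± 0.10, the GABA transaminase gene Gabat by 2.52 ± 0.17, Cyp6a17 by 2.47 ± 0.09, GILT3 by 2.42 ± 0.14 and Sr-CIII by 2.36 ± 0.10. The largest falls were those of the flight muscle genes TpnC4 (-6.71 ± 0.95) and fln (-6.64 ± 0.90), of the protease gene Jon99Fi (-6.69 ± 0.98) and of the seminal gene Dup99B (-6.34 ± 0.28). They were followed by CG12374 (-6.24 ± 0.57), CG18180 (-6.15 ± 0.64), Acbp5 (-5.98 ± 0.61), Bace (-5.86 ± 0.76), CG10911 (-5.82 ± 0.64) and yip7 (-5.81 ± 0.68).

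The chromosome 4 list passed (adjusted p = 6.74e-06, adjusted p = 0.453 with an estimated correlation), with 58 genes higher and 6 lower adjusted over the list alone. CG31997 rose by 1.26 ± 0.06, dati by 1.02 ± 0.07, mGluR by 0.98 ± 0.09 and the synaptotagmin gene Syt7 by 0.83 ± 0.09. Of the pericentric genes, 104 of 188 rose and 31 fell without a call for the list (adjusted p = 0.108), with a median of 0.24 that was -0.001 under cyclic loess. Of the H3K9 list, 13 genes rose and 1, Pof (-3.06 ± 0.20), fell without a call for the list (adjusted p = 0.0839), and under cyclic loess 5 rose and 4 fell. Pof changed by -0.59 ± 0.86 with the other-tissue score as a covariate (limma adjusted p = 0.895). Neuronal genes rose in 17 of 19 cases (adjusted p = 0.000294, adjusted p = 0.453 with an estimated correlation) and photoreceptor genes in 19 of 22 (adjusted p = 0.00405, adjusted p = 0.453 with an estimated correlation). Eye pigment genes rose in 15 of 18 cases (adjusted p = 0.0027, adjusted p = 0.388 with an estimated correlation). Adjusted over the list alone, 18 neuronal, 19 photoreceptor and 15 eye pigment genes were higher and 1 photoreceptor gene was lower.

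Genes of other body parts were lower in the double mutant as well. This held for 19 of 22 testis genes (adjusted p = 5.47e-10, adjusted p = 0.388 with an estimated correlation) and 25 of 26 accessory gland genes (adjusted p = 5.54e-12, adjusted p = 0.388 with an estimated correlation). Gut genes fell in 18 of 22 cases (adjusted p = 1.11e-06, adjusted p = 0.453 with an estimated correlation) and muscle genes in 11 of 15 (adjusted p = 0.000335, adjusted p = 0.453 with an estimated correlation), or in 7 with 4 higher when arrays were centred on their medians. Of 75 respiratory chain genes 68 fell (adjusted p = 3.05e-16, adjusted p = 0.388 with an estimated correlation), but 24 fell and 7 rose with arrays centred on their medians, with a median of -0.015. Adjusted over the list alone, 20 testis, 25 accessory gland, 18 gut, 11 muscle and 69 respiratory chain genes were lower, and 1 gut, 1 muscle and 2 respiratory chain genes higher. In all 10827 probe sets passed, 7589 higher and 3238 lower, with 440 and 1845 at 2-fold or more. Higher calls made up 70.1%, against 86.6% with each array centred on its median, 58.0% with centring on brighter probe sets and 37.3% under cyclic loess. Centring on the median moved the median change of all probe sets from 0.18 to 0.54, and the chromosome 4 median was then 0.91, against 0.28 under cyclic loess. With the other-tissue score as a covariate 12 probe sets passed, with a median standard error of 0.569. All of these except CG3397 (4.98 against 4.75) had the opposite sign to that without the covariate, so they are not calls that remained. The chromosome 4 list median per array then changed by 0.518 ± 0.361, with a 95% interval that includes 0.

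Changed genes were then placed on the chromosome arms with Fisher's exact test. On chromosome 4, 92.3% of genes changed in the egg mutant against 62.3% elsewhere (odds ratio 7.25, adjusted p = 3.44e-07), 87.7% against 67.1% in the Su(var)3-9 mutant (odds ratio 3.49, adjusted p = 0.00188) and 98.5% against 66% in the double mutant (odds ratio 33.0, adjusted p = 8.05e-10). Called higher were 84.6% against 36.3%, 76.9% against 43.2% and 89.2% against 42.1% in that order. With calls at an adjusted p under 0.01 the odds ratio of the double mutant was 5.39. Chromosome 4 genes were brighter, with a mean list median of 8.76 in the control against 7.02 to 7.17 on the large arms. These tests were not adjusted for signal. They also count genes as independent, while the estimated correlation between chromosome 4 genes was 0.146, so their p-values may be too small. Genes of the X chromosome were more often higher than other genes against the control, at 42.5% against 35.4% in the egg mutant (adjusted p = 4.33e-08), 49.8% against 42.2% in the Su(var)3-9 mutant (adjusted p = 1.22e-08) and 48.9% against 41.2% in the double mutant (adjusted p = 3.97e-09). Pericentric genes were more often higher in the egg mutant, at 49.5% against 36.3% (adjusted p = 0.000721), and in the double mutant, at 55.3% against 42.2% (adjusted p = 0.000597). In the Su(var)3-9 mutant, at 45.7% against 43.3%, they did not pass (adjusted p = 0.708). Under cyclic loess the X chromosome passed only in the egg mutant, at 20.4% against 17.4% (adjusted p = 0.00725), and not in the Su(var)3-9 (18.3% against 17.0%, adjusted p = 0.295) or double mutant (19.0% against 16.9%, adjusted p = 0.0819). Pericentric genes then passed in neither the egg (23.9% against 17.8%, adjusted p = 0.0601) nor the double mutant (18.6% against 17.2%, adjusted p = 0.626). When calls of both directions were counted together in the main scaling, neither class passed in any mutant against the control. For the egg, Su(var)3-9 and double mutants the adjusted p was 0.815, 0.469 and 0.21 for the X chromosome. For pericentric genes it was 0.135, 0.562 and 0.21. Chromosome tests under other scalings were added after the data were seen.

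The double mutant was set against the egg mutant to ask what the Su(var)3-9 mutation added in egg heterozygotes. Here too the other-tissue score differed, being higher in the egg mutant. The genes that rose most were Fbp2 by 3.57 ± 0.29 (adjusted p = 6.20e-06), Lsp2, a larval serum protein gene, by 3.40 ± 0.27, the odorant binding protein gene Obp99b by 3.07 ± 0.13 and Fbp1 by 3.02 ± 0.25. Another rise was that of hll (2.97 ± 0.14), and the largest falls were those of CG12374 (-5.21 ± 0.57), Jon65Aiv (-4.72 ± 0.98), yip7 (-4.65 ± 0.68) and Jon65Aiii (-4.60 ± 0.79) and of Dup99B (-4.28 ± 0.28). Of 65 chromosome 4 genes, 4 rose, 2 fell and 59 did not pass, adjusted over the list alone 3 and 2, with a list median of -0.01 (adjusted p = 0.908). When arrays were centred on their medians the median became 0.12, with 12 higher and 2 lower. Those that passed as reported included Gat (-0.72 ± 0.09) and Zip102B (0.66 ± 0.09), a zinc transporter. Pericentric genes passed in 31 of 188 cases, 19 higher and 12 lower, with the chitin deacetylase gene Cda4 at 1.13 ± 0.10 and TwdlG at 1.21 ± 0.14, and the list median of -0.04 was 0.08 with arrays centred on their medians (adjusted p = 0.587).

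Of 54 detoxification genes, 23 rose and 3 fell, adjusted over the list alone 29 and 4 (adjusted p = 3.58e-07, adjusted p = 0.149 with an estimated correlation). The cytochrome P450 genes Cyp6a8 and Cyp6g1 rose by 1.26 ± 0.10 and 1.24 ± 0.10, and the glutathione transferase genes GstE9 and GstD2 by 0.80 ± 0.08 and 0.84 ± 0.08. Proteasome genes rose in 23 of 40 cases and fell in 2, adjusted over the list alone 26 and 3 (adjusted p = 4.22e-05, adjusted p = 0.61 with an estimated correlation). Core subunits were among them, Prosalpha4 at 0.50 ± 0.08 and Prosbeta3 at 0.54 ± 0.09. Clock genes fell in 6 of 11 cases, adjusted over the list alone 7 (adjusted p = 0.000912, adjusted p = 0.324 with an estimated correlation). Examples were Clk (-0.84 ± 0.07), vri (-0.71 ± 0.09) and tim (-0.63 ± 0.09). Eye pigment genes rose in 7 of 18 cases, with se at 0.69 ± 0.10 (adjusted p = 0.00961, adjusted p = 0.324 with an estimated correlation).

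Genes of other body parts were again lower in the double mutant than in the egg mutant. Testis genes fell in 15 of 22 cases (adjusted p = 3.58e-07, adjusted p = 0.324 with an estimated correlation) and accessory gland genes in 20 of 26 (adjusted p = 1.09e-09, adjusted p = 0.324 with an estimated correlation). Gut genes fell in 13 of 22 cases (adjusted p = 4.22e-05, adjusted p = 0.512 with an estimated correlation), and the muscle list did not pass (adjusted p = 0.69). In these lists 17 testis, 23 accessory gland and 13 gut genes were lower adjusted over the list alone, and 7 eye pigment genes were higher. In all 2915 probe sets passed, 1485 higher and 1430 lower, of which 155 and 425 changed at least 2-fold. Higher calls were 50.9%, but 79.3% of 4745 with each array centred on its median, which moved the median change of all probe sets from 0.03 to 0.16. With the other-tissue score as a covariate 235 probe sets passed.

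The double mutant was set against the Su(var)3-9 mutant to ask what loss of 1 egg copy added beside the Su(var)3-9 mutation. Heat shock genes rose in 5 of 6 cases, with Hsp68 at 1.11 ± 0.11 (adjusted p = 6.74e-05), the small heat shock genes Hsp26 and Hsp27 at 1.10 ± 0.11 and 1.07 ± 0.13 and the co-chaperone gene DnaJ-1 at 0.51 ± 0.07. The largest rises were those of EbpII (3.06 ± 0.74, adjusted p = 0.033), CG31205 (2.83 ± 0.08), the peroxiredoxin gene Prx6c (2.35 ± 0.14), CG9029 (2.32 ± 0.45) and CG14419 (2.24 ± 0.09), of which that of EbpII did not pass without double mutant replicate 2 (adjusted p = 0.113). The serpin gene Spn47C (-2.29 ± 0.09), bcd (-2.22 ± 0.11), CG9616 (-2.13 ± 0.08), CG8100 (-2.04 ± 0.14) and Obp19a (-2.02 ± 0.16) fell most, and bcd, which encodes the maternal determinant Bicoid, had a mean log2 signal of 6.38 in the Su(var)3-9 mutant and 4.16 in the double mutant.

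The heat shock list passed (adjusted p = 1.69e-07, adjusted p = 0.169 with an estimated correlation), with 5 genes higher adjusted over the list alone. Antimicrobial and immune genes rose in 4 of 16 cases, adjusted over the list alone 7 with 1 lower: the peptide genes AttD (1.78 ± 0.13) and Def (0.72 ± 0.12), the peptidoglycan amidase gene PGRP-SC2 (0.94 ± 0.15) and the NF-kB gene Rel (0.33 ± 0.08) (adjusted p = 0.000767, adjusted p = 0.295 with an estimated correlation). Of chromosome 4 genes, 4 rose and 2 fell, adjusted over the list alone 9 and 2, with Rnf11 at -1.44 ± 0.08, CG11155 at 1.26 ± 0.09, Zip102B at 0.97 ± 0.09 and Kif3C at -0.61 ± 0.11 (adjusted p = 0.0197, adjusted p = 0.707 with an estimated correlation). Pericentric genes rose in 11 of 188 cases and fell in 6, adjusted over the list alone 16 and 6, with CG14647 at 2.01 ± 0.09 and lncRNA:CR43242 at 1.52 ± 0.12 (adjusted p = 0.0279, adjusted p = 0.707 with an estimated correlation). Without Su(var)3-9 replicate 2 or double mutant replicate 3 both lists lost their call, with adjusted p of 0.0883 for either list without the former and of 0.13 and 0.0927 without the latter, and the pericentric list also without double mutant replicate 2 (adjusted p = 0.0759). None of the 19 H3K9 genes passed (adjusted p = 0.129), nor did any neuronal gene (adjusted p = 0.426). Photoreceptor genes rose in 2 cases and fell in 1 of 22, adjusted over the list alone 9 and 1, where laza was at 0.52 ± 0.07 and the carotenoid uptake gene ninaD at -1.75 ± 0.12 (adjusted p = 0.00165, adjusted p = 0.707 with an estimated correlation). Testis and accessory gland lists lay higher in the double mutant, with medians of 0.54 (adjusted p = 0.00152, adjusted p = 0.707 with an estimated correlation) and 0.47 (adjusted p = 0.00137, adjusted p = 0.707 with an estimated correlation), although only 1 of 22 and 2 of 26 genes passed alone, and adjusted over the list alone 5 and 2. Without double mutant replicate 2, which had the highest medians of its group in both lists, these medians were 0.19 and 0.24, and the accessory gland list did not pass.

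In this comparison 971 probe sets passed, 478 higher and 493 lower, of which 69 and 85 changed at least 2-fold. Without double mutant replicate 2 the count was 610, and without Su(var)3-9 replicate 2 it was 622. Changed genes were rarer on the X chromosome, at 2.77% of 1839 genes against 6.61% elsewhere (Fisher's exact test, odds ratio 0.403, adjusted p = 3.97e-11). On the other large arms the shares were 5.66% for 2L, 6.74% for 2R, 6.99% for 3L and 6.69% for 3R.

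**Figure D3:**
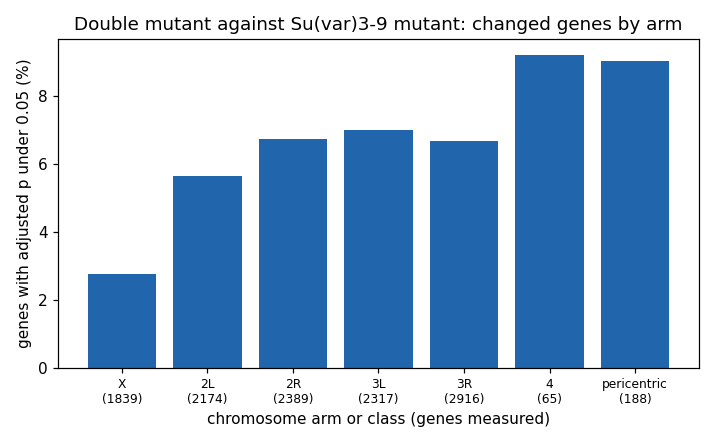
Percentage of measured genes with an adjusted p under 0.05 between the double and the Su(var)3-9 mutant, with 1 bar for each chromosome arm or class and the number of genes measured under it. The X chromosome bar stands at 2.77% and the bars of arms 2L, 2R, 3L and 3R at 5.66% to 6.99%.

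The interaction asked whether the effect of the egg mutation differed between the Su(var)3-9 states. The largest positive interactions were those of lncRNA:CR9284 (4.69 ± 0.67), the ejaculatory bulb gene Ebp (4.57 ± 1.29), CG15219 (4.54 ± 0.69) and CG2127 (4.53 ± 0.64). The largest negative ones were those of Cp15 (-4.00 ± 1.29), miple1 (-3.77 ± 0.11), CG9616 (-2.73 ± 0.12), Cks30A (-2.61 ± 0.18) and the phagocytosis receptor gene NimC1 (-2.48 ± 0.12). That of Cp15 rests on its uneven egg arrays and was -3.22 ± 3.60 with the other-tissue score as a covariate (limma adjusted p = 0.764). The mean log2 signal of miple1 was 8.34 in the control, 10.76 in the egg mutant, 10.81 in the Su(var)3-9 mutant and 9.47 in the double mutant. The interaction passed for 7627 probe sets, 2958 positive and 4669 negative. The positive share of 38.8% was 19.8% with each array centred on its median, 50.7% with centring on brighter probe sets and 66.6% under cyclic loess. Chromosome 4 genes had negative interactions in 43 of 65 cases and positive ones in 5, among them Kif3C (-1.73 ± 0.16) and CG31997 (-0.81 ± 0.09). Under cyclic loess 21 were negative and 6 positive. Their median was -0.47 (adjusted p = 1.66e-05, adjusted p = 0.414 with an estimated correlation), and adjusted over the list alone 47 were negative and 5 positive.

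Averaged over both Su(var)3-9 states, the egg main effect was largest for CG3397 (2.60 ± 0.08), Sr-CIII (2.23 ± 0.07), CG31205 (2.13 ± 0.06), Cp15 (1.93 ± 0.65) and Sr-CI (1.88 ± 0.06) among the rises and for fln (-2.81 ± 0.64), Muc68D (-2.66 ± 0.28) and TpnC4 (-2.66 ± 0.67) among the falls. It passed for 8136 probe sets, 4752 higher and 3384 lower. The value of Cp15 rests on its uneven egg arrays and was 1.57 ± 1.69 with the other-tissue score as a covariate (limma adjusted p = 0.649). Chromosome 4 genes rose in 49 of 65 cases and fell in 4 (adjusted p = 5.97e-08, adjusted p = 0.357 with an estimated correlation), and adjusted over the list alone 51 and 4. Of the comparisons averaged here, the egg mutant against the control gave 55 rises and 5 falls. The double against the Su(var)3-9 mutant, without control arrays, gave only 4 and 2. For the Su(var)3-9 main effect 33 chromosome 4 genes rose and 8 fell, adjusted over the list alone 34 and 8 (adjusted p = 0.00942, adjusted p = 0.627 with an estimated correlation), and on chromosome 4 genes were more often higher, at 50.8% against 36.3% (odds ratio 1.81, adjusted p = 0.0454), but not more often changed in either direction (odds ratio 1.20, adjusted p = 0.577). Here the Su(var)3-9 mutant against the control gave 50 rises and 7 falls, and the double against the egg mutant 4 and 2. The Su(var)3-9 main effect passed for 10262 probe sets, 7208 higher and 3054 lower, and was largest for Fbp2 (3.60 ± 0.20), Fbp1 (3.46 ± 0.18) and Obp99b (2.92 ± 0.09) among the rises and CG12374 (-5.58 ± 0.40), Dup99B (-5.51 ± 0.20) and yip7 (-5.45 ± 0.48) among the falls. The higher share moved from 58.4% to 74.2% with centring on the median and 35.6% under cyclic loess for egg, and from 70.2% to 87.8% and 35.6% for Su(var)3-9. With the other-tissue score as a covariate limma passed 80 probe sets for the interaction, 456 for the egg main effect and 0 for the Su(var)3-9 main effect, for which 10262 passed without it.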

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

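The tests of the patterns weighed here were chosen only after the results were seen, while the interaction tests and the splits of the arrays were planned.

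The interaction test of limma passed for 7627 probe sets, and for 80 with the other-tissue score as a covariate, and it includes the control, whose arrays carry more transcripts of other body parts. The same test, applied to lists with camera, passed for 14 lists. Median interactions on the log2 scale were negative for neuronal genes (-0.796), photoreceptor genes (-0.629), all chromosome 4 genes (-0.469) and the named chromosome 4 genes (-0.447). They were also negative for clock genes (-0.427), H3K9 genes (-0.369) and the named pericentric genes (-0.328). They were positive for testis (3.166), accessory gland (2.776), gut (1.993) and muscle genes (0.668), and for respiratory chain (0.509), proteasome (0.167) and detoxification genes (0.157). With arrays centred on their medians, proteasome and detoxification medians turned to -0.076 and -0.086. Under cyclic loess the medians of H3K9 genes and the named pericentric genes shrank to -0.067 and -0.079. None of these calls held with an estimated correlation, where adjusted p lay between 0.414 and 0.528.

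The first pattern is that control arrays held more testis, gut, muscle and accessory gland transcripts than mutant arrays. A shift of whole arrays by the scaling is argued against, since the testis and neuronal medians moved apart by -5.549 between the Su(var)3-9 mutant and the control. RNA of other body parts in the control preparations may lower head genes, and every control array lay below every mutant array for 4 of 6 head lists, but not for glia or head fat body. Genes of these lists were not checked for expression outside the head, so the overlap does not count against such RNA. RNA of other body parts and a direct effect of the mutations cannot be told apart, because genotype and preparation go together between groups. Within groups, over 12 arrays, no relation of the other-tissue score passed after adjustment over 4 relations: that to the accessory gland list had r = 0.975 (permutation p = 0.0154, adjusted p = 0.0526), rho = 0.937 (permutation p = 0.0267, adjusted p = 0.0534) and r = 0.937 without the 2 farthest arrays, and that to the neuronal and photoreceptor lists r = -0.504 (permutation p = 0.0263, adjusted p = 0.0526), rho = -0.797 (permutation p = 0.0217, adjusted p = 0.0534) and r = -0.55 without the 2 farthest arrays.

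The next pattern is that chromosome 4 genes lay higher in all 3 mutants than in the control. Scaling as the whole cause is argued against, since the lowest chromosome 4 median over 3 mutants and 3 other scalings was 0.198. An equal effect of egg in both Su(var)3-9 states stays open despite a median interaction of -0.469, or -0.472 with the other-tissue score as a covariate, since the interaction includes the control and that of the list median per array went from -0.286 (95% interval -0.482 to -0.09) to -0.313 (95% interval -0.903 to 0.277) with this covariate, which widened the interval without shrinking the estimate. Dilution of head RNA in the control stays open. With the other-tissue score as a covariate the medians over genes were 0.547, 0.496 and 0.544, which passed with camera at its preset correlation. The list medians per array then changed by 0.478 ± 0.233, 0.353 ± 0.370 and 0.518 ± 0.361 (n = 3), with 95% intervals that include 0. The score was 10.62 or higher on control arrays and 8.57 or lower on mutant arrays. Without overlap, this fit cannot tell dilution from the mutations. Within groups no relation passed, with r = -0.072 (permutation p = 0.809, adjusted p = 0.836), rho = -0.056 (permutation p = 0.873, adjusted p = 0.873) and r = -0.093 without the 2 farthest arrays between the chromosome 4 list and the neuronal and photoreceptor lists, and r = 0.044 (permutation p = 0.836, adjusted p = 0.836), rho = 0.063 (permutation p = 0.855, adjusted p = 0.873) and r = 0.134 without the 2 farthest arrays between it and the score.

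The last pattern is that X-linked genes changed less often than others between the double and the Su(var)3-9 mutant. Their expression level as the whole cause is argued against by an odds ratio of 0.395 (95% interval 0.295 to 0.528) after adjustment for mean signal over 11888 genes. Among 10223 genes not at least 2-fold lower in the Su(var)3-9 mutant than in the control the odds ratio was 0.41 (95% interval 0.299 to 0.551). That argues against genes with such large falls as the whole cause. Both intervals count genes as independent and may be too narrow. The filter keeps genes with smaller falls and uses the Su(var)3-9 arrays of the comparison itself. Scarcity of other-tissue transcripts on the X therefore stays open. Autosomal differences between the stocks could give this pattern, and all 4 large autosomal arms had more changed genes than the X (Fisher's exact p of 7.77e-06 or lower), but the stocks cannot be told apart from the egg mutation.

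Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave 9550 calls for egg against the control with 0 as the highest other, 11580 with 3 for Su(var)3-9, 10827 with 0 for the double mutant, 2915 with 0 for the double against the egg mutant, and 971 with 0 for the double against the Su(var)3-9 mutant, so 1 split of 10 reached the real count in each. Among 100 assignments, only the real one reached the real count for the interaction (7627, highest other 5583), for the egg main effect (8136, highest other 7627) and for the Su(var)3-9 main effect (10262, highest other 8372). Assignments for the interaction also broke up the main effects. The highest other count of the egg main effect equals the interaction count, since an assignment can keep whole genotypes together. These assignments therefore do not test any of these effects alone, and no conclusion is drawn from them.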

How the results depend on the processing

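The other-tissue score as a covariate and the omission of 2 arrays together were chosen only after the results were seen. Replicate numbers did not pair the arrays: of 18 pairs with the same number, 1 had a correlation of deviations over 0.1 (range -0.36 to 0.101, mean -0.076), and 3 of 12 arrays correlated best with their own number. With a replicate block the counts were 9318, 11207, 10502, 2542 and 761 for the pair comparisons in the order of the report, 7258 for the interaction and 7838 and 9738 for the main effects. The block ended the call of pericentric genes in the egg mutant (median 0.215, adjusted p = 0.0523). The first technical array stood for control replicate 1, and the alternatives that need the second were not run. The direction and call of all 180 named values held under cyclic loess and both centrings. In the double against the Su(var)3-9 mutant the call of EbpII was lost with the block, only the groups compared, trend and robust eBayes and array weights, that of Rel with the block and without 2 arrays, that of CG9029 with only the groups compared and that of Kif3C without 2 arrays. Calls of Cp15 in the interaction and the egg main effect were lost with trend and robust eBayes. EbpII, Rel and Cp15 made up the 23 calls lost when single arrays were left out. The level of dim probe sets is limited by their signal over background.

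A 1.5-fold minimum, which tests fewer changes by construction, left 4931, 4732 and 4728 calls for the egg, Su(var)3-9 and double mutants against the control, 1297 and 392 for the double against the egg and Su(var)3-9 mutants, 4805 for the interaction and 2147 and 2516 for the main effects. Centring on array medians gave 17374 and 17151 for the Su(var)3-9 and double mutants, 4745 for the double against the egg mutant, 11988 for the interaction and 17130 for the Su(var)3-9 main effect. Array weights gave 4905 for the double against the egg mutant. Omission of Su(var)3-9 replicate 3 and double mutant replicate 2 gave 564 for the double against the Su(var)3-9 mutant. Except where fewer arrays or changes enter by construction, the cause was not tested.

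With the other-tissue score as a covariate, 113, 10 and 12 probe sets passed against the control, 235 for the double against the egg mutant, 80 for the interaction, and 456 and 0 for the main effects. In the double mutant all of these except CG3397 had turned sign, and in the Su(var)3-9 mutant CG8997 and Sgp had. The score separates the control from the mutants (10.62 or higher against 8.57 or lower), so the median standard error grew from 0.103 to 0.367, 0.583 and 0.569 against the control, and these fits cannot divide the groups from the score. Of 180 named values 62 kept direction and call, 82 kept only the direction and 36 reversed. Reversed gut medians were 0.95, 2.745 and 1.753 against the control, 0.757 for the double against the egg mutant and -1.641 for the interaction. Reversed accessory gland medians were 0.618, 0.441, 0.733, 0.327 and -0.352 in that order. The cause was not tested. In the egg mutant LManIII reversed to 2.07, TpnC4 to 2.44, Mal-A4 to 1.49, Jon25Biii to 4.195, fln to 2.43, Mal-A7 to 0.47 and Mal-A1 to 1.74. In the Su(var)3-9 mutant Ebp reversed to 9.62, EbpII to 6.59, Acp53C14b to 6.89, Acp36DE to 7.49, lncRNA:CR9284 to 1.86, CG9920 to 2.20, CG17376 to 4.24, ocn to 2.33 and Acp53Ea to 6.81. In the double mutant TpnC4 reversed to 4.08, Jon99Fi to 10.58, fln to 3.06, CG12374 to 4.07, CG18180 to 5.61, Acbp5 to 4.24, Bace to 7.57, CG10911 to 5.08, yip7 to 6.64 and mGluR to -0.03. Against the egg mutant Jon65Aiv reversed to 1.65 and Jon65Aiii to 0.65. Interactions of lncRNA:CR9284, Ebp, CG15219 and CG2127 reversed to -0.87, -6.45, -0.97 and -0.41, egg main effects of fln and TpnC4 to 0.13 and 0.61, and Su(var)3-9 main effects of CG12374 and yip7 to 1.62 and 3.23. Of these reversed named values only that of Ebp in the interaction passed (adjusted p = 0.0261). The pericentric list passed in the double mutant (0.269, adjusted p = 0.0358).

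With an estimated correlation the medians of chromosome 4 did not pass against the control (0.543, 0.465 and 0.552), for the double against the Su(var)3-9 mutant (0.06) or for the interaction (-0.469), nor did pericentric genes in the egg mutant (0.215) or the double against the Su(var)3-9 mutant (0.054). With fry, which tests lists without other genes, pericentric genes passed in the Su(var)3-9 mutant (0.184), the double mutant (0.241) and the interaction (-0.184), chromosome 4 did not pass for the double against the Su(var)3-9 mutant (0.06), and the detoxification list of the Su(var)3-9 mutant had the opposite direction (median 0.099, adjusted p = 0.00559). Centring on brighter probe sets ended the pericentric call of the egg mutant (0.102, adjusted p = 0.0501). Without probe sets below the 40th percentile, pericentric genes passed in the double mutant (0.321) and chromosome 4 did not for the double against the Su(var)3-9 mutant (0.06, adjusted p = 0.0695). No odds ratio of chromosome 4 or pericentric genes changed its call at an adjusted p of 0.1 or 0.01 or with hand lists. The cause was not tested.

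Leaving out each array in turn gave 8685 to 9648 calls for the egg, 9947 to 11607 for the Su(var)3-9 and 9465 to 11041 for the double mutant against the control, 2004 to 3472 and 610 to 1148 for the double against the egg and Su(var)3-9 mutants, 6858 to 8110 for the interaction, and 7431 to 8559 and 9008 to 10584 for the main effects. Chromosome 4 medians were 0.536 to 0.596, 0.408 to 0.484, 0.506 to 0.6, -0.042 to 0.027, 0.043 to 0.107 and, for the interaction, -0.52 to -0.436. Pericentric medians were 0.208 to 0.232, 0.162 to 0.207, 0.237 to 0.269, -0.048 to -0.019, 0.045 to 0.071 and -0.199 to -0.163. The pericentric call of the egg mutant was lost without control replicate 2, egg replicate 2, Su(var)3-9 replicates 1 or 3 or double mutant replicate 2. The gut list of the double against the Su(var)3-9 mutant ranged from -0.32 to 0.35, with the latter reversed without Su(var)3-9 replicate 3 (adjusted p = 0.0306).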

Other observations

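The accessory gland list, the shared-control simulation and the count of strongly raised probe sets were chosen only after the data were seen, while the gene lists below were fixed in advance.

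Odorant binding genes rose in 16 of 29 cases and fell in 1 in the Su(var)3-9 mutant against the control, and adjusted over the list alone in 16 and 1 (adjusted p = 0.00809, adjusted p = 0.503 with an estimated correlation), or in 28 and 1 with arrays centred on their medians. In the double mutant 19 rose and 1 fell, adjusted over the list alone 19 and 1 (adjusted p = 0.0123, adjusted p = 0.453 with an estimated correlation), or 12 and 4 under cyclic loess, and in the egg mutant 14 rose and 4 fell without a call (adjusted p = 0.227). Head fat body genes passed for the double against the egg mutant, with 5 of 13 higher and 2 lower, adjusted over the list alone 7 and 2 (adjusted p = 0.00559, adjusted p = 0.324 with an estimated correlation). Antimicrobial genes rose there in 7 of 16 cases and fell in 1, adjusted over the list alone 9 and 3, with the peptide gene AttD at 1.58 ± 0.13 (adjusted p = 0.0083, adjusted p = 0.324 with an estimated correlation). Of 4 Turandot genes 2 rose, among them TotC by 1.80 ± 0.21, and 2 adjusted over the list alone (adjusted p = 0.0255, adjusted p = 0.324 with an estimated correlation). Of 6 heat shock genes 3 rose, adjusted over the list alone 4, with Hsp68 at 0.71 ± 0.11 (adjusted p = 0.0396, adjusted p = 0.512 with an estimated correlation). Photoreceptor genes fell there in 7 of 22 cases and rose in 1, adjusted over the list alone 12 and 1 (adjusted p = 0.00752, adjusted p = 0.685 with an estimated correlation), and odorant binding genes rose in 6 of 29 and fell in 3, adjusted over the list alone 7 and 3 (adjusted p = 0.0255, adjusted p = 0.596 with an estimated correlation). With arrays centred on their medians these were 3 photoreceptor genes lower and 2 higher, and 11 odorant binding genes higher and 1 lower. In the same comparison testis, accessory gland and gut genes were lower, with medians of -1.56, -2.24 and -1.52.

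Detoxification genes fell in 24 of 54 cases and rose in 14 in the egg mutant against the control, adjusted over the list alone in 24 and 14, with Cyp4p2 at -3.53 ± 0.12, while the list median of -0.14 was 0.09 with arrays centred on their medians (adjusted p = 0.0115, adjusted p = 0.368 with an estimated correlation). The genes of the list went both ways, and Cyp6a17 rose by 2.37 ± 0.09. In the double against the Su(var)3-9 mutant 11 rose and 11 fell without a call (adjusted p = 0.613), with the glutathione transferase genes GstE3 and GstE7 at -1.64 ± 0.09 and -1.67 ± 0.10. In that comparison 1 of 4 female-enriched genes, fit, fell by 1.15 ± 0.18, and the list median was -0.14 (adjusted p = 0.0227, adjusted p = 0.707 with an estimated correlation). Of 4 male-enriched genes 2 fell, adjusted over the list alone 3 with 1 higher (adjusted p = 0.026, adjusted p = 0.295 with an estimated correlation). Lists passed there without a single gene past the threshold for the proteasome, with a median of -0.12 and 4 genes lower adjusted over the list alone (adjusted p = 0.000767, adjusted p = 0.707 with an estimated correlation), and the respiratory chain, with 0.07 (adjusted p = 0.0255, adjusted p = 0.851 with an estimated correlation). No glia list passed in the egg (adjusted p = 0.198), Su(var)3-9 (adjusted p = 0.317) or double mutant (adjusted p = 0.194), nor did ovary lists (adjusted p = 0.685, 0.288 and 0.148) or ribosomal protein lists (adjusted p = 0.693, 0.0909 and 0.0896). None of the lists of a chromosome arm passed in any contrast, and no difference in the share of changed genes within 2 Mb of egg or Su(var)3-9 passed (Fisher's exact test, lowest adjusted p = 0.29).

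In the Su(var)3-9 mutant 20 probe sets were at least 8-fold higher than in the control, of which 15 passed as lower in the double than in the Su(var)3-9 mutant, in a set chosen for high values in the latter, and 5 were changed less than 2-fold in the double mutant. Of these 20, 10 had no gene name. CG40485 was singled out after its values were seen, since its probe sets differed. The dimmer one had mean log2 signals of 6.04 in the control, 5.99 in the egg mutant, 9.56 in the Su(var)3-9 mutant and 11.27 in the double mutant, with n = 3 each, and the brighter one rose by 0.50 ± 0.12 in the Su(var)3-9 mutant.

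Calls were shared widely between comparisons with the same control arrays. The egg and Su(var)3-9 mutants shared 4848 higher and 2843 lower probe sets, against 2661 and 616 for independent lists of these sizes, and 248 went opposite ways. The egg and double mutants shared 5203 and 2936, against 2426 and 612, with 138 opposite, and the Su(var)3-9 and double mutants 6339 and 2974, against 3366 and 562, with 55 opposite. Unchanged groups simulated 20 times against shared controls gave 0 shared calls, a same-sign share of 66.6% and a correlation across probe sets of 0.489. The observed same-sign shares were 81.9%, 85.0% and 91.6%, the correlations 0.881, 0.923 and 0.968, and the covariances 0.709, 0.697 and 1.01 beside a simulated covariance of 0.00971. Probe sets are not independent observations, and part of the excess may come from the shared controls, which are too few to split. With the other-tissue score as a covariate, an alternative chosen after the data were seen, 113, 10 and 12 probe sets passed for the egg, Su(var)3-9 and double mutants. These are not all remaining calls. In the double mutant all except CG3397 had turned sign, and in the Su(var)3-9 mutant CG8997 and Sgp had.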
